A study of Mus musculus with 8 samples.

How the data were processed

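Total RNA of snap-frozen liver from 8 male mice aged 6 weeks was amplified, biotin-labelled and hybridised to Affymetrix mouse gene arrays, 1 per mouse, per the labels' protocols. The genotype label of each sample set the groups: 4 mice with TAK1 and caspase 8 deleted in liver parenchymal cells (Tak1/Casp8) and 4 with TAK1 deleted in those cells and Rip3 knocked out (Tak1/Rip3). Replicate numbers only name the arrays, and no label pairs mice across the groups. The labels used here give no litter, cage, scan or batch, so none was tested, and a difference in background or handling that follows the genotype cannot be told apart from it.

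The deposited values are log2 intensities normalised with RMA, per the submitters' processing notes, which name no version. RMA subtracts background, aligns the distributions of the probes and summarises the probes of a probe set, so a shift shared by most genes would be largely removed and small differences near the background are compressed. The values used here carry no detection call, and no depth exists for arrays, whose number limits the precision. Each value belongs to a probe set of about the size of an exon. Of 223771 probe sets, 206316 had exactly 1 gene symbol in the platform annotation, 3734 had several and 13721 had none. The annotation is old, so 2571 symbols were updated where an old symbol was a synonym of 1 gene in a RefSeq gene table of assembly GRCm38.p6. That table was used for names and for which genes neighbour each other, and 19456 of the 19560 symbols matched it. The position of each probe set and the genome build behind the annotation are not given in the sources used here, so no coordinates are printed.

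From these values 1 value per gene and array was computed as the median over the probe sets with that symbol alone, giving 19560 genes with a median of 8 probe sets, of which 1890 rest on 1. Probe sets with several symbols or none named no gene. No filter on dim genes was set. The median over probe sets hides a change in a part of a transcript, which is why the targeted genes are also given by probe set. Genes in families of near-identical copies can share probes, and their values are uncertain.

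Tests were run in R 4.3.3, and the moderated gene tests, camera and fry used limma 3.58.1. The Welch test, the exact permutation of list means, Fisher's exact test and Dixon's test did not use limma. Figures were drawn in matplotlib 3.10.9 under Python 3.11.15. The model had 1 term for the group over all 8 arrays (lmFit and eBayes, two-sided), and adjusted p means Benjamini-Hochberg over all 19560 genes, called under 0.05. A fold is 2 to the power of the log2 difference. Counts "adjusted over the list alone" apply Benjamini-Hochberg to the p-values of that list's measured genes. Gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the 34 lists tested, and again with the correlation estimated for each list, with fry, and by exact permutation of the arrays on the mean over the members. The 35 lists, 26 of pathways and 9 of cell type markers, held 477 genes of which 446 were measured. Alas2, Slc4a1, Hbb-b1 and Epb42 were the measured erythroid genes.

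The genes named in the text followed a rule set, like the lists, the tests and most alternatives, before the data were examined. It took the 3 targeted genes, the 12 largest increases and 12 largest decreases among genes with an adjusted p under 0.05 whose groups did not overlap (leaving out symbols of unnamed transcripts), and in each list the up to 4 measured members with the smallest adjusted p. A few other list members, such as Cyp7a1, Glul, Alb, Mlkl, Hspa5, Gpc3, Igf2bp3, Cyp2e1, Col1a1, Krt7 and Krt19, were named after their values were seen, as well-known members of their lists.

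Alternatives were quantile normalisation, a shift of each array to 1 median, the mean, the brightest or the brighter probe sets of a gene, filters at the 30th and 50th percentile of mean level, eBayes with trend and robust settings, array weights, a Welch test (unmoderated variances, separate for each group), thresholds of 0.01 and 0.10, omission of genes within 10 Mb of the targeted loci, and omission of each array in turn. Omission of both of the least correlated arrays, a clock-gene score as a covariate and the permutation of arrays per list were added after the data had been seen.

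The gene test was tested on simulated data of 19560 genes, in which 200 genes had been changed. Each gene had its moderated spread from this comparison, equal in both groups and independent of the other genes. The test recovered 29.9% of the genes changed by 0.5 on the log2 scale, 95.5% at 1 and 100% at 2. With 6 false among 156 calls, differences of 0.5 were mostly missed. In the data spreads can differ between the groups and genes are correlated, so these rates may not carry over. In a simulation of the 34 lists, camera called both lists shifted by 0.5 and no other. No simulation was run with the correlations estimated in the data, such as 0.80 among G2 and M phase genes and 0.73 among fibrosis genes. The simulated result therefore does not show how often camera at its preset correlation makes false calls in such lists.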

Results

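Gene expression was measured in liver tissue of 8 male mice aged 6 weeks, with 1 Affymetrix mouse array per mouse. All 8 mice had lost the kinase TAK1, the product of Map3k7, in liver parenchymal cells (LPC). In 4 of them caspase 8, the protease that starts death receptor apoptosis, was deleted in LPC as well. The other 4 carried a knockout of Rip3 (gene Ripk3), the kinase that passes on the necroptosis signal, in the whole animal. The groups are named Tak1/Casp8 and Tak1/Rip3 here, and each difference is Tak1/Casp8 minus Tak1/Rip3. The stated purpose of the comparison was to find genes on which apoptotic and necrotic signalling act differently. Mice with TAK1 intact were not analysed here, so a gene that was higher in one group may equally be read as lower in the other. The deposited values were log2 intensities normalised by RMA, and 19560 genes were tested. Array medians lay between 8.06 and 8.16, and the correlation across genes between any 2 arrays lay between 0.975 and 0.993. The lowest mean correlation with the own group was that of Tak1/Casp8 replicate 4 (0.985) and of Tak1/Rip3 replicate 2 (0.987). The number of arrays, 4 per group, limits the precision of every value.

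The targeted genes differed in the direction of the labels. Casp8 was 2.47-fold lower in the Tak1/Casp8 livers (log2 difference -1.31 ± 0.11 SE, n = 4 per group, limma adjusted p = 0.000123), with 9.97 ± 0.13 (SD) against 11.27 ± 0.13. All 11 of its probe sets were lower there, by -1.95 to -0.10, and 9 of them passed the test. Ripk3 was 1.97-fold higher in the Tak1/Casp8 livers, and so lower in the Rip3 knockouts (0.98 ± 0.17, limma adjusted p = 0.00782), with 7.90 ± 0.09 against 6.92 ± 0.38. Of its 10 probe sets 9 were higher and 3 passed. Map3k7, targeted in both groups, differed by -0.08 ± 0.10 (limma adjusted p = 0.695), and its 11 probe sets by -0.12 to 0.79. The position of the probe sets relative to the deleted exons is not given in the sources used here, and cells other than LPC keep Casp8 and Map3k7. The Ripk3 call was lost when the brightest probe set stood for the gene (-0.04) or when each gene kept unmoderated variances, separate for each group (adjusted p = 0.150).

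**Figure D1:**
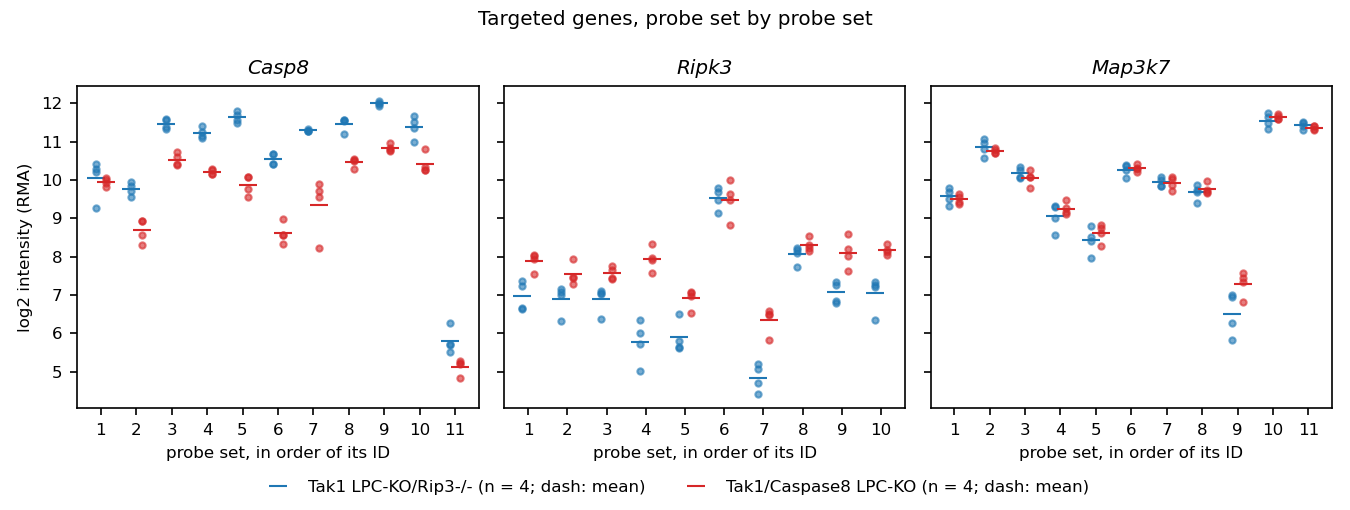
Log2 intensity (RMA) of each probe set of Casp8, Ripk3 and Map3k7, in the order of the probe set IDs, with 1 point per mouse (n = 4 per group) and a dash at each group mean. The 11 Casp8 probe sets are lower in the Tak1/Casp8 livers by -1.95 to -0.10, while the brightest of the 10 Ripk3 probe sets differs by -0.04.

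Between the groups, 1308 of the 19560 genes (6.69%) differed at an adjusted p under 0.05 in limma, 516 higher and 792 lower in the Tak1/Casp8 livers. Of these, 801 differed by 1.5-fold or more (272 higher, 529 lower) and 299 by 2-fold or more (80 higher, 219 lower). In 2861 genes (14.6%, against 2.86% by chance) the 4 values of one group all lay beyond the 4 of the other, and 1262 of the 1308 were among them. Besides Casp8, 13 of the genes named by rule passed under each alternative setting in which they were tested. A filter at the 50th percentile of level left out Skint7, Cd163 and Raet1e. Of the 13, Cib3, Skint7, Cd14, Cd163, Hp and Gsdmd were higher, and Gldn, Serpina3k, Mmd2, Raet1e, Ly6d, Mmp12 and Prom1 were lower. Skint7 and Serpina3k rest on 1 probe set each, so the choice of probe sets could not change their values. The count of 1308 was 706 without Tak1/Rip3 replicate 1, 737 without Tak1/Rip3 replicate 4 and 765 without Tak1/Casp8 replicate 2. It was 115 with unmoderated variances separate for each group, which changes 2 choices at once, and 759 with the brightest probe set of each gene. Those settings ended the call of 83 and 35 of the 99 untargeted named genes that passed.

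The genes furthest below their Tak1/Rip3 level in the Tak1/Casp8 livers included fetal liver genes and a steroid enzyme. Akr1c18, a hydroxysteroid dehydrogenase that inactivates progesterone, was 40.3-fold lower (log2 difference -5.33 ± 0.31 SE, n = 4 per group, limma adjusted p = 1.62e-05). The fetal growth factor Igf2 was 16.0-fold lower (SE 0.47 on the log2 scale), the neighbouring noncoding RNA H19 10.7-fold (-3.42 ± 0.66) and alpha-fetoprotein, Afp, 10.7-fold (-3.41 ± 0.33). The ranking took called genes whose groups did not overlap, which left out Cyp4a14 (7.55-fold lower). Also among its 12 largest negative differences were Gldn (10.9-fold), Cyp2b9 (8.51-fold), Mmd2 (5.38-fold), Raet1e, a ligand of the NK cell receptor NKG2D (5.12-fold), and the cyclin Ccnb2 (4.66-fold). Serpina3k, Serpina1d and Serpina1c completed them, at 9.63-fold, 8.43-fold and 6.55-fold lower. These 3 protease inhibitors rest on 1, 1 and 2 probe sets and have near-identical copies, so which copy differed is uncertain. With the brightest of its 2 probe sets Serpina1c differed by -0.09 (adjusted p = 0.638). Its fold therefore comes from the dimmer probe set and averages 2 unlike ones. With the brightest probe sets Akr1c18 differed by -3.75, Gldn by -4.36 and Afp by -4.88 (-2.56 with its brighter probe sets, and Igf2 -4.78). H19 differed by -3.04 with its brightest probe set (adjusted p = 0.0639) and by -4.02 without Tak1/Casp8 replicate 3. In the Tak1/Casp8 livers Akr1c18 (5.58), Gldn (6.34) and Raet1e (6.31) lay under the lower quartile of those arrays (6.47 to 6.49), so their folds are uncertain. Here and below the lower quartile is that over single probe sets, not over gene values.

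By the same ranking, the 12 genes furthest above their Tak1/Rip3 level in the Tak1/Casp8 livers included secreted plasma proteins and receptors. The serum amyloid Saa2 was 10.8-fold higher (3.43 ± 0.36 SE, n = 4 per group, limma adjusted p = 0.000716), and the orosomucoids Orm3 and Orm2 were higher by 3.23 and 2.32 on the log2 scale. Serpina7, which encodes thyroxine-binding globulin, was 8.21-fold higher. Pigr, the epithelial receptor that carries polymeric immunoglobulin into bile, was 4.71-fold higher (2.24 ± 0.16, limma adjusted p = 8.29e-05), and Jchain, which joins the immunoglobulin units it carries, was 4.08-fold higher. The immunoglobulin kappa locus Igk was 4.72-fold higher, the lipopolysaccharide receptor Cd14 4.14-fold and the haemoglobin scavenger receptor Cd163 3.95-fold. The remaining 3 were Cib3 (6.71-fold), Skint7 (5.55-fold, 1 probe set) and the desmoglein Dsg1c (4.15-fold). Orosomucoid and serum amyloid genes also have close copies. Of these, Saa1 differed by only 0.31 (limma adjusted p = 0.421), Saa3 by 1.30 and Orm1 by 0.95. In the Tak1/Rip3 livers Cd163 (5.77), Skint7 (5.77), Dsg1c (5.09) and Igk (5.21) lay under the lower quartile of those arrays (6.51 to 6.52). The folds of these 4 genes and of the orosomucoid and serum amyloid genes are therefore uncertain. With the brightest probe sets Saa2 differed by 2.50, Orm2 by 1.38, Jchain by 1.20 and Igk by 1.58. The Igk call, from 2 probe sets, was lost there (adjusted p = 0.196), with the brighter probe sets (0.148), with unmoderated separate variances (0.189) and without both of the least correlated arrays (0.0742). The Orm2 call was lost without Tak1/Rip3 replicate 1 or 4 (adjusted p = 0.0597 and 0.0580), and without Tak1/Rip3 replicate 3 Orm2 differed by 2.91.

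**Figure D2:**
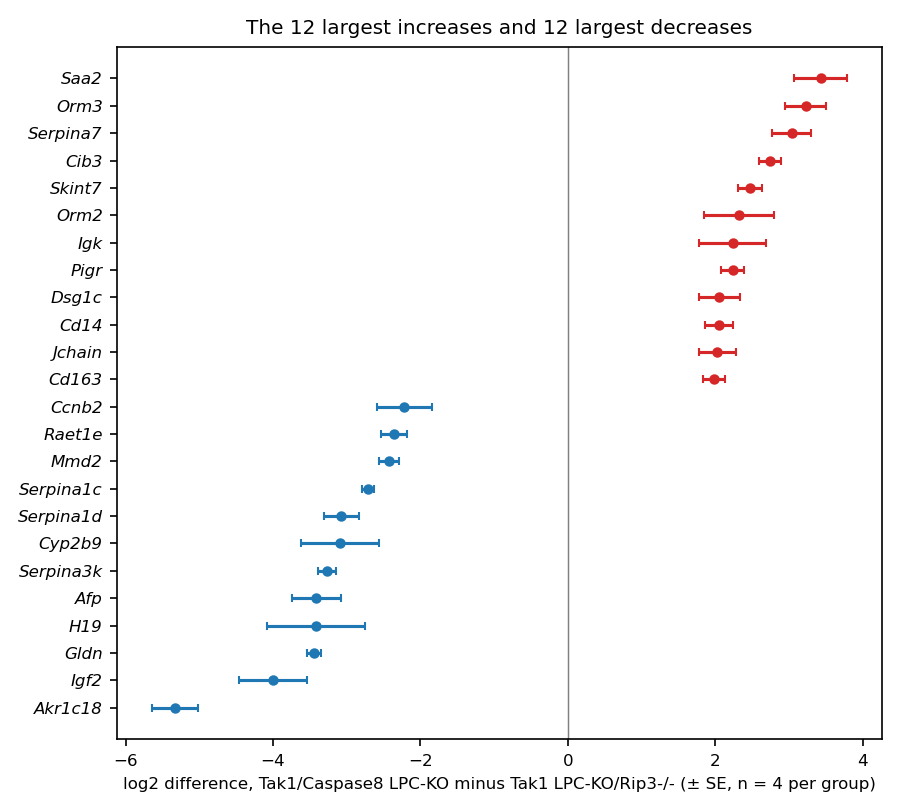
Log2 difference (Tak1/Casp8 minus Tak1/Rip3, horizontal axis) of the 12 genes furthest above (red) and the 12 furthest below (blue) their Tak1/Rip3 level, with bars of ± 1 SE from limma (n = 4 per group). Only called genes whose groups did not overlap were ranked. The values run from -5.33 for Akr1c18 to 3.43 for Saa2.

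The 35 gene lists fixed in advance held 446 measured genes, and 34 of them had enough members for a test. With limma's camera at its preset correlation of 0.01, 15 lists were called, 5 higher and 10 lower in the Tak1/Casp8 livers. With an estimated correlation camera called 0 of the 34, with 7 at an unadjusted p under 0.05 and a lowest adjusted p of 0.241. The rotation test fry, which does not compare a list with other genes, called 15, of which 11 were also called by camera. It lost the pericentral, interferon, fibrosis and unfolded protein lists and added basolateral efflux, hepatocyte identity, T and NK cells, and B and plasma cells. In an exact two-sided permutation of the arrays (35 splits) 11 lists had the smallest p this design allows, 0.029, which is 0.088 after adjustment. Among the lists called by camera, those of NF-kB, PPARalpha, lipogenesis, interferon and fibrosis had larger exact p-values, from 0.057 to 0.11. Camera calls are therefore given with the count of genes that passed singly.

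Genes of dividing cells were lower in the Tak1/Casp8 livers. All 19 measured genes of the G2 and M phases passed the test with lower values (also 19 adjusted over the list alone), with a median log2 difference of -1.46. The cyclins Ccnb2 and Ccna2 were 4.66-fold and 3.81-fold lower, the mitotic kinesin Kif20a 4.37-fold, and the kinases Plk1 and Aurka 3.72-fold and 2.64-fold. Of 18 genes of the G1 and S phases 9 were lower (17 adjusted over the list alone, and 15 singly without both of the least correlated arrays), with a median of -0.68. Among them were cyclin D1 (Ccnd1, -1.28 ± 0.23 SE, n = 4 per group), both ribonucleotide reductase subunits Rrm2 (-1.60 ± 0.27) and Rrm1 (-0.97 ± 0.19), and thymidylate synthase Tyms (-1.03 ± 0.18). Camera called both lists (adjusted p = 3.21e-19 and 4.94e-12), with adjusted p = 0.241 for each with an estimated correlation. Beside them, the markers of stellate cells had a median difference of -0.25 and those of T and NK cells of -0.10.

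Of 14 oncofetal and liver tumour markers, 5 were lower and 1 higher in the Tak1/Casp8 livers (8 and 1 adjusted over the list alone). Besides Afp, Igf2 and H19, the surface protein Ly6d was 3.18-fold lower (-1.67 ± 0.13 SE, n = 4 per group, limma adjusted p = 0.000100). Igf2bp3, an oncofetal RNA-binding protein, differed by -0.65. The trypsin inhibitor Spink1 was the exception, 3.24-fold higher (1.70 ± 0.26). Gpc3, another marker of liver tumours, differed by -0.74 and did not pass. Camera called the list lower (adjusted p = 2.79e-05), with adjusted p = 0.241 with an estimated correlation.

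**Figure D3:**
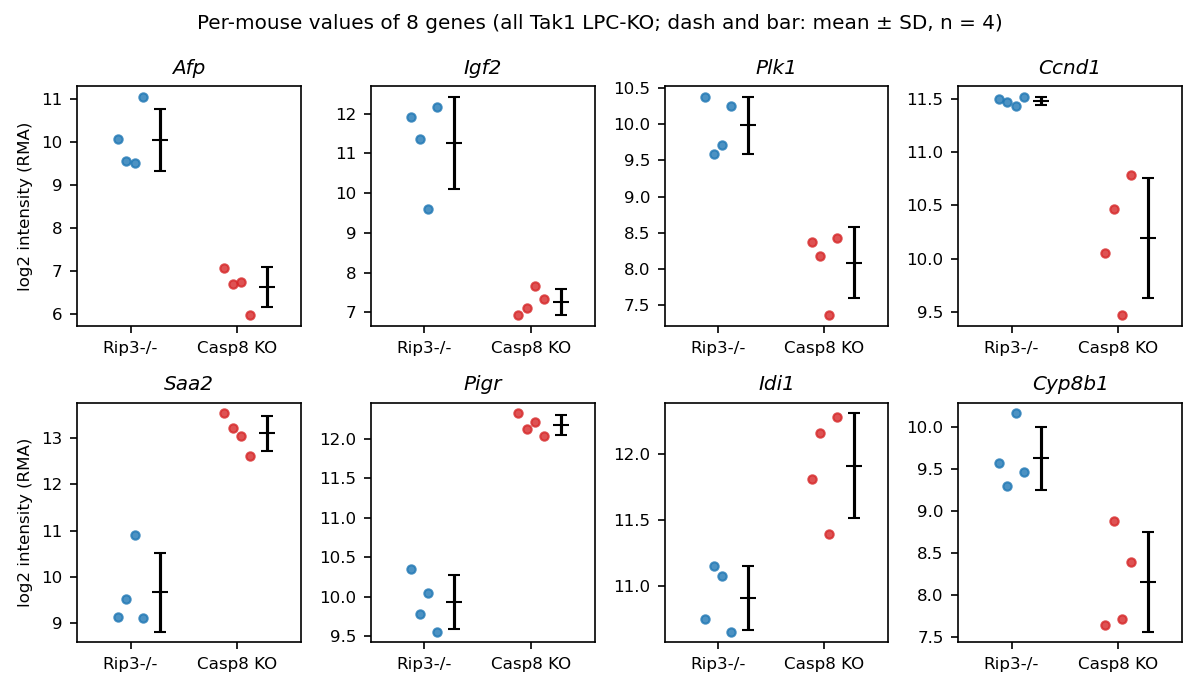
Log2 intensity (RMA, vertical axes, which do not start at 0) of 8 genes in each mouse (points), with a dash and bar for mean ± SD (n = 4 per group). Afp, Igf2, Plk1, Ccnd1 and Cyp8b1 are lower and Saa2, Pigr and Idi1 higher in the Tak1/Casp8 livers, with no overlap between the groups.

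Acute phase genes were higher in the Tak1/Casp8 livers. Of 20 measured, 12 passed with higher values (14 adjusted over the list alone) and all 20 differences were positive, with a median of 0.58. Besides Saa2 and Orm2, the lipopolysaccharide-binding protein Lbp was 2.01-fold higher (1.01 ± 0.15 SE, n = 4 per group), haptoglobin (Hp) 1.61-fold and the metalloreductase Steap4 1.57-fold. Of 18 genes of NF-kB signalling and inflammatory cytokines 6 were higher and 1 lower (8 and 2 adjusted over the list alone). The neutrophil chemoattractant Cxcl1 was 2.97-fold higher (1.57 ± 0.20), the monocyte chemoattractant Ccl2 2.64-fold (1.40 ± 0.24) and the apoptosis inhibitor Birc3 1.52-fold, while the adhesion molecule Vcam1 was 1.67-fold lower. Camera called both lists higher (adjusted p = 1.83e-12 and 0.000558), with adjusted p = 0.241 and 0.243 with an estimated correlation. The NF-kB call was lost with the brightest probe sets (adjusted p = 0.292), and Vcam1 without Tak1/Rip3 replicate 1, 2 or 4 or Tak1/Casp8 replicate 2 (adjusted p = 0.0682 to 0.0919).

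Of 19 interferon-induced genes 4 were lower in the Tak1/Casp8 livers (5 adjusted over the list alone): the antiviral genes Rsad2 (2.24-fold), Oasl1 (1.73-fold), Usp18 (-0.59) and Ifit1 (1.44-fold). Camera called the list lower (median -0.20, adjusted p = 0.00478), with adjusted p = 0.420 with an estimated correlation and 0.106 with fry, and an exact permutation p of 0.11. The lowest score of the list over the 8 arrays, -0.21, was that of Tak1/Rip3 replicate 2, against that direction. Of 14 AP-1 and immediate early genes Fos was higher (0.43 ± 0.09 SE, n = 4 per group; 4 adjusted over the list alone) and the list was not called (adjusted p = 0.274). The Oasl1 call held in every leave-one-out fit, whereas Rsad2 was lost without Tak1/Rip3 replicate 1, 3 or 4 (adjusted p = 0.0508 to 0.0576) and Ifit1 and Usp18 without any 1 of 6 arrays, all but Tak1/Rip3 replicate 2 and Tak1/Casp8 replicate 4 (up to 0.131). Fos was lost without Tak1/Rip3 replicate 1 or 3 or Tak1/Casp8 replicate 1 or 2 (up to 0.0674).

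Genes of lipid metabolism differed in opposite directions. Of 12 measured genes of cholesterol synthesis 7 were higher in the Tak1/Casp8 livers (9 adjusted over the list alone) and all 12 differences were positive, with a median of 0.70. They included Idi1 (2.00-fold, 1.00 ± 0.19 SE, n = 4 per group), Nsdhl (1.89-fold), lanosterol synthase Lss (1.72-fold) and Fdps (1.53-fold). Of 10 lipogenic genes, fatty acid synthase Fasn (1.76-fold) and Gpam (1.56-fold) were higher (6 adjusted over the list alone). Of 12 genes of PPARalpha and fatty acid oxidation 5 were lower (7 adjusted over the list alone), among them the fatty acid hydroxylases Cyp4a14 (7.55-fold) and Cyp4a10 (3.23-fold), the thioesterase Acot1 (-1.85, at a level of 6.29, under the lower quartile) and Pdk4, which restrains pyruvate oxidation (2.33-fold). Camera called all 3 lists (adjusted p = 3.26e-08, 0.000366 and 1.19e-05), with adjusted p = 0.250, 0.277 and 0.329 with an estimated correlation. The score of the PPARalpha list in Tak1/Casp8 replicate 4 (0.19) lay inside the Tak1/Rip3 range (0.17 to 0.50), so 1 array of the group lacked the difference, and without both of the least correlated arrays 8 of its genes were lower. Fasn was lost without Tak1/Rip3 replicate 1 or 3 or Tak1/Casp8 replicate 2 (adjusted p = 0.0553 to 0.0583), and Cyp4a14 without any 1 of 6 arrays, all but Tak1/Rip3 replicate 2 and Tak1/Casp8 replicate 4 (up to 0.0931), and without the latter it differed by -3.75.

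Few bile acid genes differed. Cyp8b1, the sterol hydroxylase required for cholic acid, was 2.76-fold lower in the Tak1/Casp8 livers (-1.46 ± 0.28 SE, n = 4 per group, limma adjusted p = 0.0123). The conjugating enzymes Slc27a5 and Baat were 1.71-fold and 1.64-fold higher, and the other 9 of 12 genes of bile acid synthesis did not pass, among them Cyp7a1, the rate-limiting enzyme (-0.59). The transporter Abcc3, which exports conjugates to the blood, was 1.78-fold higher (0.83 ± 0.15), the only one of 9 basolateral and cholestasis genes that passed, and the uptake carrier Slco1a4 was 1.83-fold higher, the only one of 11 genes of uptake and canalicular export. Adjusted over the list alone, 2 higher and 1 lower, 1 and 1, and 2 and 1 passed in these lists. Camera called none of the 3 (adjusted p = 0.399, 0.232 and 0.517), and for bile acid synthesis its direction, higher, differs from the sign of the median (-0.01). Fry called the basolateral list higher (adjusted p = 0.0409), with an exact permutation p of 0.63. The Slco1a4 call was lost without Tak1/Rip3 replicate 1, 2 or 4 or Tak1/Casp8 replicate 1 or 2 (adjusted p = 0.0510 to 0.0702).

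Of 12 genes of the hepatocytes around the central vein 6 were lower in the Tak1/Casp8 livers (7 adjusted over the list alone), with a median of -0.56. The Wnt receptor partner Lgr5 was 2.88-fold lower (-1.52 ± 0.21 SE, n = 4 per group), Lect2 2.40-fold, the cation transporter Slc22a3 2.10-fold and the Wnt target Axin2 1.66-fold. Glul and Cyp2e1, also pericentral, differed by 0.14 and -0.02 and did not pass. Of 12 periportal genes Aldh1b1 was lower (1.76-fold) and Hsd17b13 higher (1.31-fold; 1 lower and 4 higher adjusted over the list alone), and of 14 hepatocyte identity genes clotting factor F9 (1.43-fold), Tdo2 (1.41-fold) and the transcription factor Cebpa (1.30-fold) were higher (4 adjusted over the list alone), while albumin, Alb, differed by -0.04. Camera called the pericentral list (adjusted p = 0.000819, and adjusted p = 0.374 with an estimated correlation) but not the periportal (0.113) or the identity list (0.0623), whereas fry called the identity list higher (adjusted p = 0.0163) and not the pericentral list (0.0627). Axin2 differed by 0.17 with its brightest probe set, and Slc22a3 was lost without Tak1/Rip3 replicate 1 (adjusted p = 0.0575). Calls were also lost for F9 without Tak1/Rip3 replicate 1 or 4 or Tak1/Casp8 replicate 2, for Tdo2 without Tak1/Rip3 replicate 4 or Tak1/Casp8 replicate 2 or 3 (both up to 0.0620), for Hsd17b13 without any array but Tak1/Casp8 replicate 4 (up to 0.112) and for Cebpa without any 1 array (up to 0.134).

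Of the genes of cell death itself few differed. Gsdmd, the pore-forming protein of pyroptosis, was 1.47-fold higher in the Tak1/Casp8 livers (0.56 ± 0.09 SE, n = 4 per group, limma adjusted p = 0.00662), the only one of 12 necroptosis and pyroptosis genes that passed (1 higher and 1 lower adjusted over the list alone). The necroptosis effector Mlkl differed by 0.12. Bak1, which permeabilises mitochondria, was 1.35-fold lower, the only one of 16 apoptosis genes that passed (2 adjusted over the list alone). Camera called neither list (adjusted p = 0.601 and 0.527). The Bak1 call was lost without Tak1/Rip3 replicate 1 (adjusted p = 0.0516).

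Of 12 p53 targets 3 were lower in the Tak1/Casp8 livers (4 adjusted over the list alone): the receptor Eda2r (-1.19 ± 0.14 SE, n = 4 per group, at a level of 6.43, under the lower quartile), Phlda3 (1.97-fold) and Ccng1 (1.34-fold). Of 13 genes of the unfolded protein response 3 were higher (4 higher and 1 lower adjusted over the list alone): asparagine synthetase Asns (2.63-fold), Herpud1 (2.19-fold) and Chac1 (1.75-fold). The chaperone Hspa5 differed by 0.08, and Asns and Chac1 are also known targets of ATF4. Of 10 NRF2 targets Srxn1 was lower (1.58-fold) and Gpx2 higher (1.82-fold; 3 lower and 1 higher adjusted over the list alone). Camera called the p53 and unfolded protein lists (adjusted p = 0.000477 and 0.0180, with adjusted p = 0.241 and 0.374 with an estimated correlation) but not NRF2 targets (0.0829). The unfolded protein call was lost with fry (0.0797), with the brightest probe sets (0.131), without Tak1/Rip3 replicate 2 (0.0740) or without Tak1/Casp8 replicate 2 (0.104), and its score in Tak1/Casp8 replicate 4 (-0.20) lay inside the Tak1/Rip3 range. Calls were also lost for Gpx2 without Tak1/Rip3 replicate 4 (0.0586) and for Ccng1 without any array but Tak1/Casp8 replicate 2 (up to 0.127).

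Sex-biased and xenobiotic genes differed in a few members. Of 8 genes typical of female liver 3 were lower in the Tak1/Casp8 males (5 adjusted over the list alone): Cyp2b9 (8.51-fold, -3.09 ± 0.53 SE, n = 4 per group), Hao2 (-1.67) and A1bg (-1.29). Of 11 male-biased genes the urinary protein Mup20 was 2.16-fold higher (2 higher and 2 lower adjusted over the list alone), and of 11 xenobiotic genes Cyp2c55 was 4.28-fold lower (1 adjusted over the list alone). Camera called the female-biased list lower (adjusted p = 0.000217, and adjusted p = 0.241 with an estimated correlation), and not the male-biased (0.527) or xenobiotic list (0.121). Cyp and Mup genes have near-identical copies, so the member that differed is uncertain, as are the sizes for Hao2 (4.99) and A1bg (5.53), which lay under the lower quartile in the Tak1/Casp8 livers. A1bg was lost without Tak1/Casp8 replicate 2 (adjusted p = 0.0529).

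Of 19 fibrosis and matrix genes 4 were lower in the Tak1/Casp8 livers (4 adjusted over the list alone): the macrophage elastase Mmp12 (4.26-fold, -2.09 ± 0.14 SE, n = 4 per group, limma adjusted p = 6.54e-05), Mmp2 (1.90-fold) and the collagens Col6a3 (1.85-fold) and Col4a1 (1.35-fold). The fibrillar collagen Col1a1 differed by -0.31 and did not pass. Of 11 stellate cell markers Reln (1.57-fold) and the retinol esterase Lrat (1.51-fold) were lower (2 adjusted over the list alone). Camera called both lists (adjusted p = 0.000434 and 0.00835), with adjusted p = 0.493 and 0.241 with an estimated correlation. The fibrosis call was lost with fry (adjusted p = 0.129, exact permutation p = 0.11) and without Tak1/Casp8 replicate 4 (median -0.12, adjusted p = 0.0540), whose median deviation in these genes was -0.74 and lowest of the 8 arrays, while those of Tak1/Casp8 replicates 1 (0.11) and 3 (0.04) lay inside the Tak1/Rip3 range. Mmp2 was lost without any array but Tak1/Casp8 replicate 1 or 3 (up to 0.117), Col4a1 without Tak1/Rip3 replicate 1, 3 or 4 or Tak1/Casp8 replicate 2 or 4 (up to 0.0912), and Reln without any Tak1/Rip3 array or without Tak1/Casp8 replicate 2 (up to 0.0944).

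Markers of the other cells of the liver differed singly. In the B and plasma cell list Jchain was 4.08-fold higher and the B cell receptor gene Cd79a and the B cell antigen Ms4a1 were lower in the Tak1/Casp8 livers by -1.38 and -1.11, both under the lower quartile there (8 measured; 1 higher and 3 lower adjusted over the list alone). Of 15 macrophage markers Cd14 was higher and Gpnmb (2.94-fold) and Trem2 (1.57-fold), both genes of lipid-associated macrophages, were lower (2 higher and 4 lower adjusted over the list alone). Of 14 cholangiocyte and progenitor markers osteopontin, Spp1, was 1.96-fold higher and Prom1, also known as CD133, 3.38-fold lower (-1.76 ± 0.10 SE, n = 4 per group; 1 higher and 4 lower adjusted over the list alone), while the bile duct keratins Krt7 and Krt19 both differed by -0.30. The receptors Cxcr2 (0.87 on the log2 scale, under the lower quartile in the Tak1/Rip3 livers) and Csf3r (1.30-fold) were higher among 11 neutrophil markers and Gpr182 (1.49-fold) among 12 endothelial markers (2 and 1 adjusted over the list alone). Camera called none of these 5 lists (adjusted p = 0.121, 0.990, 0.121, 0.0673 and 0.337), and for macrophages its direction, lower, differs from the sign of the median (0.06). Fry called the B and plasma cell list lower (adjusted p = 0.0355), with an exact permutation p of 0.11. Calls were lost in leave-one-out fits for Gpnmb (6 arrays, not Tak1/Casp8 replicate 3 or 4), Trem2 (7 arrays, not Tak1/Casp8 replicate 3), Gpr182 (7 arrays, not Tak1/Rip3 replicate 4) and Csf3r (any array), with adjusted p up to 0.139. Without both of the least correlated arrays Cxcr2, Csf3r, Gpr182, Gpnmb and Trem2 no longer passed. In that fit 0 endothelial markers were higher and 1 was lower.

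In 4 lists limma called 0 genes: Notch and YAP targets (12 measured, 3 at an unadjusted p under 0.05), T and NK cell markers (14 measured, 3), pancreas acinar markers (7 measured, 1) and erythroid markers (4 measured, 0). Adjusted over the list alone limma again called 0. With unmoderated separate variances the count was 0 here too, but so it was among the 19 G2 and M phase genes, so that 0 decides nothing. The YAP target Ankrd1 differed by -0.83 (limma adjusted p = 0.0619), the cytotoxic granule gene Nkg7 by -0.32, the pancreas proteases Cela3b and Prss2 by 0.25 and 0.31, and the haemoglobin gene Hbb-b1 by 0.44. Camera called none of the first 3 lists (adjusted p = 0.517, 0.114 and 0.261), and the erythroid list was too short to test. Fry called the T and NK cell list lower (adjusted p = 0.0323, 11 of 14 differences negative), with an exact permutation p of 0.057.

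**Figure D4:**
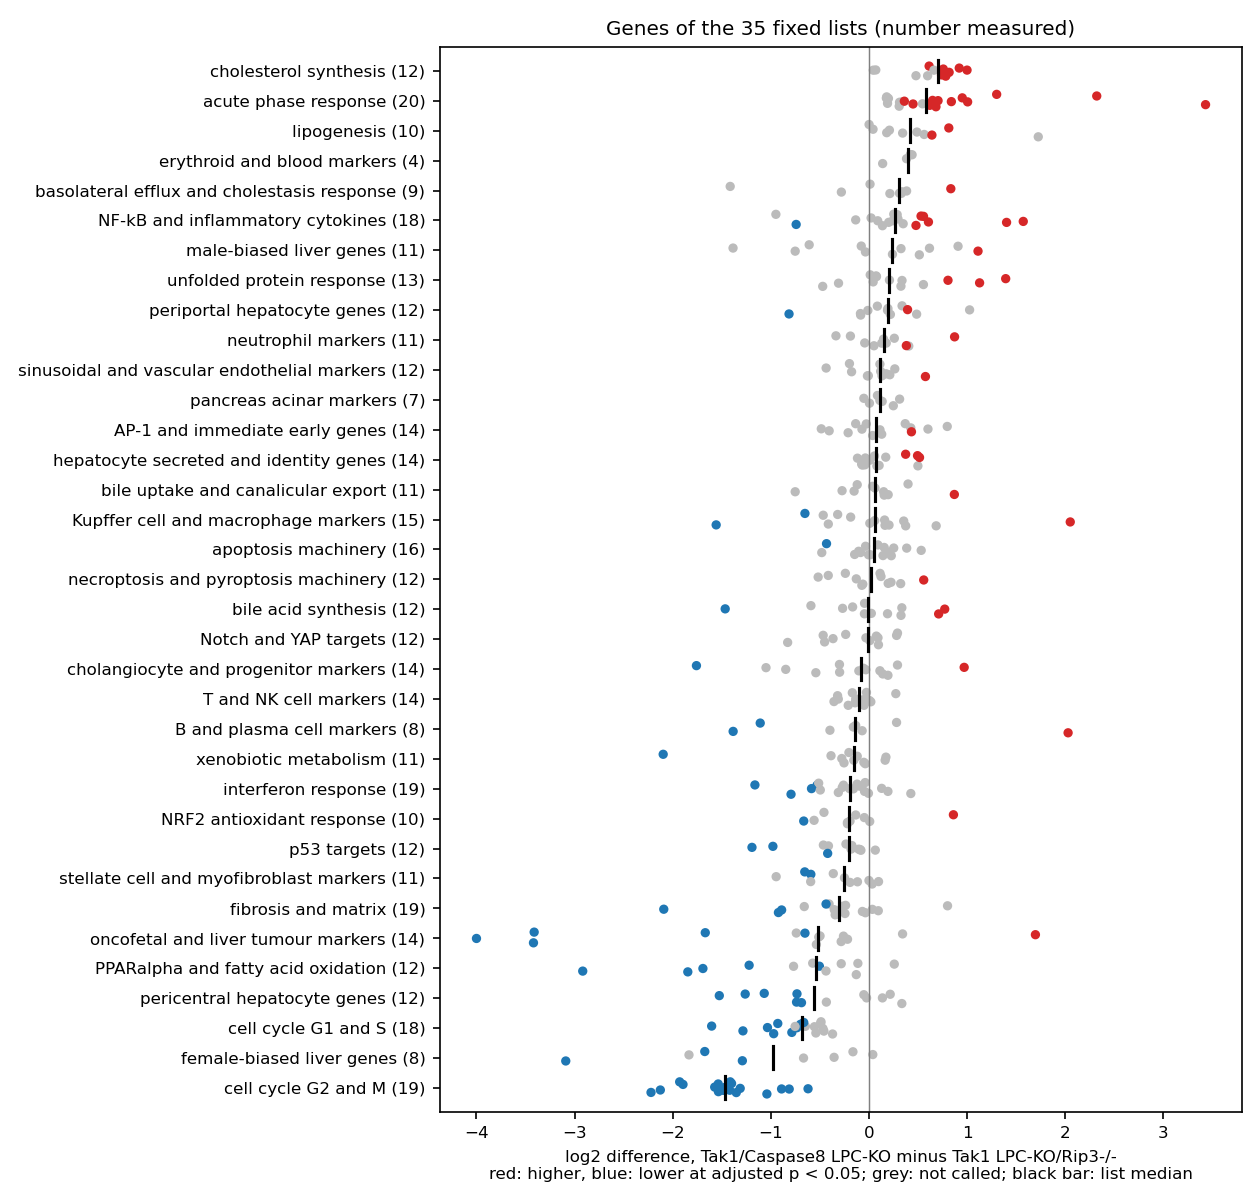
Log2 difference (Tak1/Casp8 minus Tak1/Rip3, horizontal axis) of each measured gene of the 35 lists (points), with the number measured in brackets and a bar at the list median. Red and blue points passed limma at an adjusted p under 0.05, higher and lower, and the medians run from -1.46 for G2 and M phase genes to 0.70 for cholesterol synthesis.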

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

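The omission of both least correlated arrays, the cell type comparison, the test of the range of values and the test of genes near the targeted loci were chosen after the results they bear on had been seen. The splits of the arrays were set before their results were seen. The clock-gene test was written before its values were seen, for genes not yet looked at, and read by array afterwards.

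In 20 of 328 comparisons of the 4 arrays of a group (6.1%, where chance gives about 1 in 20), 1 array lay apart from the other 3, with a gap to the nearest, as a share of the group's range, above Dixon's 95% critical value. In Tak1/Casp8 replicate 2 the lowest values were those of Nkg7 (0.990), Cd79a (0.946), Ugt1a1 (0.941), Junb (0.895) and Abcb1a (0.870). In Tak1/Casp8 replicate 3 Ccnb2 (0.944; 7.53 against a mean of 9.39 in the other 3), Raet1e (0.911), Cyp2b10 (0.905) and Kif20a (0.893; 6.44 against 7.79) were lowest and Ankrd1 (0.876) highest. In Tak1/Casp8 replicate 4 Cyp4a10 (0.934; 12.5 against 11.0), Cyp2c55 (0.892), Tyms (0.849) and Acot1 (0.832; 7.30 against 5.96) were highest, and in Tak1/Casp8 replicate 1 Cxcl1 (0.878). In the Tak1/Rip3 group, Ripk3 was lowest in replicate 1 (0.835; 6.36 against 7.11), Ctrb1 highest in replicate 2 (0.887), and in replicate 3 Slc4a1 (0.892) and Gldn (0.864) were highest and Hey1 (0.892) lowest.

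Of the 35 splits of the 8 arrays into 4 and 4, only the real one (1 of 35) gave as many called genes. It gave 1308, against 1 in the highest other split. For genes of 1.5-fold or more the real split was also the only one (1 of 35), with 801 against 1 in the highest other split. With 35 splits the smallest possible p is 0.029. The other splits mix the groups, which adds the group difference to the spread and by itself lowers their counts. They therefore do not show how large a count chance would give. For gene lists called by camera, 3 of the 35 splits reached 15, with 15 the highest of the others, so chance cannot be excluded for the number of lists.

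The first pattern weighed is the lower level of G2 and M phase genes in the Tak1/Casp8 livers, with a median of -1.46 and lower values in all 19. A different share of a cell type that divides as a whole would have to bring its markers along, but outside the B and plasma cell list the lowest median was -0.25, in stellate cells, and no median less 2 standard errors reached 0.5 times the median of the pattern, -0.73. For B and plasma cells it did (median -0.15, approximate SE 0.46), so they cannot be told apart in this way. The SE treats the genes of a list as independent, yet the estimated correlation was 0.46 in cholangiocyte and 0.32 in macrophage markers. It is too small there, so these cell types are not set aside either. A change in part of a cell type, such as cells with Prom1 (-1.76) and Epcam (-1.05) or macrophages with Gpnmb (-1.56), was not tested. The 2 least correlated arrays do not carry the pattern, as without both the median was -1.84. What stays open is that hepatocytes themselves may divide less without caspase 8 than without Rip3. The cell types and parts of cell types left undecided above stay open too. So do an effect of the loss of Rip3 in other cells and an untested difference in background or handling, both of which follow the genotype.

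The second pattern is that Tak1/Rip3 replicate 2 (0.987) and Tak1/Casp8 replicate 4 (0.985) had the lowest mean correlation with their groups. The margin was small, with 0.988 in Tak1/Casp8 replicate 3. Dixon's test flagged neither array on its mean correlation, its SD over genes or its clock-gene score. Another time of day may explain Tak1/Rip3 replicate 2. Its score of clock genes not yet looked at deviated by 1.03 from its group, against at most 0.676 in the 6 arrays other than these 2. For Tak1/Casp8 replicate 4 that score deviated by only -0.0644. The clock-gene score used as a covariate deviated there by 0.844, against 1.78 in Tak1/Rip3 replicate 2 and -0.945 in Tak1/Rip3 replicate 4. Arntl was 7.09 in Tak1/Casp8 replicate 4 against 8.29 to 8.74 in its group. The 2 scores differ and each sees only 1 axis of the cycle, so another time of day stays open for this array too. A compressed range of values, from weaker labelling or degraded RNA, stays open for both, with an SD over genes of 2.04 and 2.02 against at least 2.07 in the others. No biological explanation was tested for these 2 arrays.

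The third pattern is that the genes called include several with little spread within the groups, such as Serpina1c. A sequence variant under the dimmer of its 2 probe sets could also produce this, as the brightest alone did not pass. Stretches of genome carried along with the targeted loci would put such genes near those loci. Of the genes within 10 Mb of Casp8, Ripk3 or Map3k7 5.11% (24 of 470) were called against 6.72% of the others (Fisher's exact p = 0.190). None (0) of the 24 ranked genes with the largest differences lay within that distance. Map3k7 is targeted in both groups, so genome around it may not differ, yet its neighbours are pooled in the 470. The shares therefore do not decide the matter for Casp8 and Ripk3 singly. Variants elsewhere in the genome, from a mixed strain background, were not tested and stay open.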

How the results depend on the processing

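The alternatives were chosen before the values were seen, except the omission of both least correlated arrays and the clock-gene covariate, which were added afterwards; under these 1456 and 1350 genes were called. The 1308 called genes became 759 with the brightest probe set of each gene (476 shared), 115 with unmoderated variances separate for each group (103 shared), 406 and 2130 at an adjusted p under 0.01 and 0.10, and 706 to 1347 with 1 array left out (706 without Tak1/Rip3 replicate 1, 737 without Tak1/Rip3 replicate 4, 765 without Tak1/Casp8 replicate 2). The 801 of 1.5-fold or more became 525 above the 50th percentile of level, where fewer genes are tested, 69 with those variances and 570 to 887 with 1 array left out. Camera called 15 gene lists, 0 with an estimated correlation (7 at an unadjusted p under 0.05; fry called 15) and 14 to 18 under the other settings. Casp8 was lower under every setting run (-1.37 to -1.09, adjusted p at most 0.0203). Ripk3 was -0.036 with its brightest probe set and 0.98 with the separate variances (adjusted p = 0.150). Map3k7 changed sign to 0.094 with the mean and 0.088 with the brightest probe set, uncalled in each. Of the 158 other named genes, 1 with a call reversed, Axin2, at 0.17 with the brightest probe set. Sign changes of uncalled genes numbered 4 with the brightest probe set and 1 with the brighter probe sets. They numbered 2 without Tak1/Casp8 replicate 4 and 1 without both least correlated arrays. Of the 99 untargeted named genes that were called, 74 kept their call with each array left out and 13 under each setting in which they were tested. Among the 13, Skint7, Cd163 and Raet1e fell below the filter at the 50th percentile. Skint7 and Serpina3k rest on 1 probe set each, which the choice of probe sets cannot change. The unmoderated separate variances ended 83 calls and the brightest probe set 35. The cause of lost calls was not tested. Fewer arrays leave less power, yet 1347 genes were called without Tak1/Casp8 replicate 4 and 1456 without both least correlated arrays. The count therefore also depends on which array is left out. Moderation and a variance common to the groups were dropped together, so their parts cannot be separated. Shifting the arrays to 1 median raised the share of called genes that were higher from 39.4% to 49.1%. The balance of higher and lower among all called genes therefore rests on the scaling. Among genes of 1.5-fold or more, lower ones stayed in excess. There 272 of 801 were higher, 306 of 784 with quantile normalisation and 334 of 800 with 1 median. Signal over background limits dim genes, since RMA compresses differences near the background.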

Other observations

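The gene families of this part and the test of imprinted genes were chosen after the results had been seen, whereas the test of plasma cells was written before the values of its genes were seen.

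Histone genes were lower in the Tak1/Casp8 livers in 14 of 48, with the other 34 not called (median -0.25), among them H2ac15 (-1.70), H2ac4 (-1.18), H2bc8 (-1.02) and H3c15 (-0.97). The direction held under both other scalings of the arrays (12 lower in each, medians -0.24 and -0.21). The number was 8 without Tak1/Rip3 replicate 1 or 4 or Tak1/Casp8 replicate 2 and 9 without Tak1/Casp8 replicate 3. Immunoglobulin genes were higher in 7 of 16, with the other 9 not called (median 0.79), among them Igk (2.24), Igkv6-25 (1.77), Igh (1.36) and Iglv1 (1.29). They were higher in 9 under both other scalings (medians 0.81 and 0.83), and in 4 without Tak1/Rip3 replicate 4 or Tak1/Casp8 replicate 2. Genes of these families have near-identical copies.

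The higher immunoglobulin genes, with Jchain, may come from more plasma cells in the liver. Plasma cell genes not used before had a median of 0.0327 over 8 genes, with Derl3 at 0.55, Sdc1 at -0.11 and Prdm1 at -0.02. Members that go both ways decide nothing, so this stays open. Among the B cell genes, Cd79a and Ms4a1 were lower, both at low levels, while Blk and Cd22 differed by -0.07 and -0.16 and were not called.

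Igf2, H19 and Meg3 (-1.96 ± 0.17 SE, n = 4 per group) are imprinted and were all lower in the Tak1/Casp8 livers, so a joint fall of imprinted growth genes may be at work. The other 15 imprinted growth genes had a median of -0.176, with Rian (-1.68) and Igf2r (-0.34) lower and Sgce (1.13) higher. This too stays open, since the members went both ways. Rian lies in the same cluster as Meg3, as H19 does with Igf2.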
